A study of Mus musculus with 9 samples.

How the data were processed

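The deposited table held estimated counts per gene for 54232 Ensembl genes in 9 RNA-seq libraries of mouse neural stem cells. Per the labels' protocols, total RNA was extracted with a silica column kit, fragmented and copied with random primers, and nothing there says that strand was kept. Per the submitters' processing notes the authors used FastQC, cutadapt, Trimmomatic 0.36, STAR 2.5.0a and RSEM with the genome build GRCm38. These notes give no order of steps, and the annotation release and the counting settings are not given in the sources used here. The deposited estimated counts were whole numbers already, so rounding changed none of them. RSEM shares reads that fit several genes between them by a model, so values of paralogs, pseudogenes and overlapping or antisense genes are uncertain. Symbols came from GENCODE M21, which is on GRCm38, by Ensembl identifier; 54079 identifiers matched and 153 did not. Coordinates are from that annotation.

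Samples were grouped by the treatment in their labels into shNT, sh900 and sh902, with 3 libraries each. Totals ran from 23212472 to 32392496 counts per library, so genes under about 1 CPM rested on few counts. Replicates were checked for duplicates by a chi-square test of counts over genes; the lowest value per degree of freedom within a group was 59.0, far above that of 1 library deposited again. All analyses ran in R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood F test with robust dispersions, TMM factors and edgeR's default expression filter by group (17602 genes, 99.9% of all counts). All 9 libraries entered 1 model with 3 groups, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of F. The main fit had no block, and the fit with the date label as a replicate block was its first alternative. These choices, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

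The pairing rests on the titles, in which libraries of different groups carry the same date; what the date marks is not stated. Deviations from the group means correlated at 0.40 to 0.63 between the libraries of 30 August, at 0.46 to 0.64 between those of 3 September and at -0.66 to 0.30 between libraries with different labels. The undated libraries share only the absence of a date, and correlated at 0.08 to 0.40. Of the 9 libraries, 8 correlated best with a library of their own label. The exception was the undated control. It correlated at 0.145 and 0.080 with the undated sh900 and sh902 libraries, and at 0.285 and 0.302 with the sh900 and sh902 libraries of 3 September. The dated libraries were therefore taken as paired and the undated ones as possibly paired, and blocked values stand beside the main ones where they change a call. A fit on the 6 dated libraries alone was run with and without the block.

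Gene lists (27, of which 25 had at least 5 measured members) were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. The sex-linked list had 2 measured members and the microglia list 2, too few to test. Members were counted by the edgeR calls adjusted over all genes and over the list alone. The rule for named genes took Phf2, the 12 higher and 12 lower genes with the largest mean change among those called with both hairpins, at a mean of at least 1 CPM and leaving out numbered gene models. It further took, for each single contrast, the 5 higher and 5 lower called genes with the groups fully apart, and up to 4 called members of each list with the smallest adjusted p. The rule was applied to the blocked fit because the fit without the block called no gene. Counts of 0 were set to a floor of 3 counts per library for a bound on a fold; such floors cover counting error only, and PCR reads are not independent molecules.

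The scripts were tested on simulated counts for 17602 genes with the real means, library sizes and dispersions, in which 100 genes changed 2-fold and 100 changed 4-fold in both hairpin groups. For the mean of both hairpins edgeR recovered 3% of the 2-fold and 61% of the 4-fold changes without the block, and 41% and 84% with it. Of its calls, 8 of 72 without the block and 21 of 146 with it were genes that had not been changed, above the nominal 5%; for DESeq2 1.42.0 these were 49 of 154 and 66 of 213. A list of 30 genes changed 1.5-fold was called in both fits, and 0 of 24 unchanged lists were called in either, where simulated genes vary independently. Alternatives tried were DESeq2, limma-voom, RLE factors, library size alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, fits on the compared groups alone, a minimum of 1.5-fold, the replicate block, the dated libraries alone and each library left out in turn. Limma-voom, scaling by library size alone and the settings varied on top of the block, other than the dated libraries alone, were chosen after seeing the data.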

Results

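RNA-seq was used to compare primary mouse embryonic neural stem cells after treatment with a non-targeting short hairpin RNA (shNT) or with 1 of 2 hairpins against Phf2, sh900 and sh902. Short hairpin RNAs are processed in the cell into small RNAs that lower the transcript they match. Phf2 encodes a protein of the KDM7 family of histone lysine demethylases. The tissue was labelled as the brain subventricular zone, and the cells grew on laminin with fibroblast and epidermal growth factors. RNA was taken 3 days after treatment. Each of the 3 groups held 3 libraries, 9 in all, with 1 undated library, 1 carrying the date 30 August and 1 carrying 3 September. What the dates mark is not given in the labels, and nothing there says whether replicates were separate cultures or animals, so p-values measure the spread between these libraries, which may be partly technical. Library totals ran from 23212472 to 32392496 estimated counts, and 17602 genes passed the expression filter. The comparisons asked which genes differ when Phf2 is lowered, and which of these differ with both hairpins.

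Phf2 (ENSMUSG00000038025, chromosome 13, 48801750 to 48871119 on GRCm38) was lower in every hairpin library than in every control library. It stood at 52.6 ± 3.85 CPM (counts scaled to the library's total; SD, n = 3) with shNT, 20.1 ± 5.28 with sh900 (SD, n = 3) and 23.4 ± 5.75 with sh902 (SD, n = 3). Against the control library with the same date label, sh900 left 35.2% in the undated library, 28.3% on 30 August and 52.4% on 3 September. The matching values for sh902 were 44.4%, 32.1% and 57.7%. A two-sided exact permutation test of log2 CPM for the 6 hairpin libraries against the 3 controls gave p = 0.0119 over 84 splits. With 3 libraries against 3 the exact permutation p was 0.1 for each hairpin, the smallest that 10 splits allow, and 0.6 between the hairpins. These permutations did not use the date labels, and sh902 left more Phf2 than sh900 at each label. In edgeR's quasi-likelihood test the mean log2 fold change of both hairpins was -1.28 ± 0.20 (SE, adjusted p = 0.182) without a term for the date label and -1.32 ± 0.16 (SE, adjusted p = 0.00519) with the replicate block, a term for the date label. The blocked log2 fold changes of the single hairpins were -1.43 ± 0.19 (SE, adjusted p = 0.00864) and -1.21 ± 0.19 (SE, adjusted p = 0.0119).

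**Figure D1:**
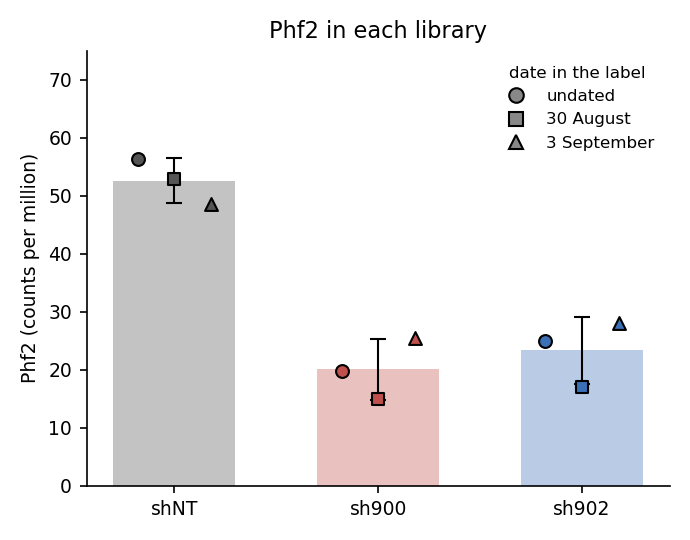
Phf2 in CPM (vertical axis) in each library (points; circles undated, squares 30 August, triangles 3 September) of shNT, sh900 and sh902; bars are group means and error bars the SD of 3 libraries. The control mean is 52.6 and the hairpin means are 20.1 and 23.4.

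The dated libraries separated first by date label. The first principal component of the 500 most variable genes held 57.8% of their variance, with the 30 August libraries between 23.9 and 46.3 and the 3 September libraries between -53.4 and -19.7. On that axis the undated control lay at -34.2, away from the undated sh900 library at 13.6 and the undated sh902 library at 14.5. The 3 control libraries were far apart in proliferation and glial genes. Mki67, a marker of cycling cells, stood at 291 CPM in the undated control, 869 on 30 August and 60.1 on 3 September. Gfap, the astrocyte intermediate filament gene, was highest where Mki67 was lowest, and Pdgfra, a receptor of oligodendrocyte precursors, stood at 74.7, 11.1 and 266 CPM. Among the hairpin libraries Mki67 ranged from 194 CPM with sh900 on 30 August to 523 CPM in the undated sh902 library. The second component, with 17.4% of the variance, placed the control below both hairpin libraries at every label. The undated control lay at -5.96 against 22.4 and 25.7. The values were -26.6 against -9.02 and -10.2 on 30 August, and -24.1 against 12.9 and 14.9 on 3 September. The third, with 7.53%, separated sh900 (-21.7 to -7.80) from sh902 (13.97 to 14.8). Mki67, Gfap and Pdgfra were picked as examples after their levels were seen.

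**Figure D2:**
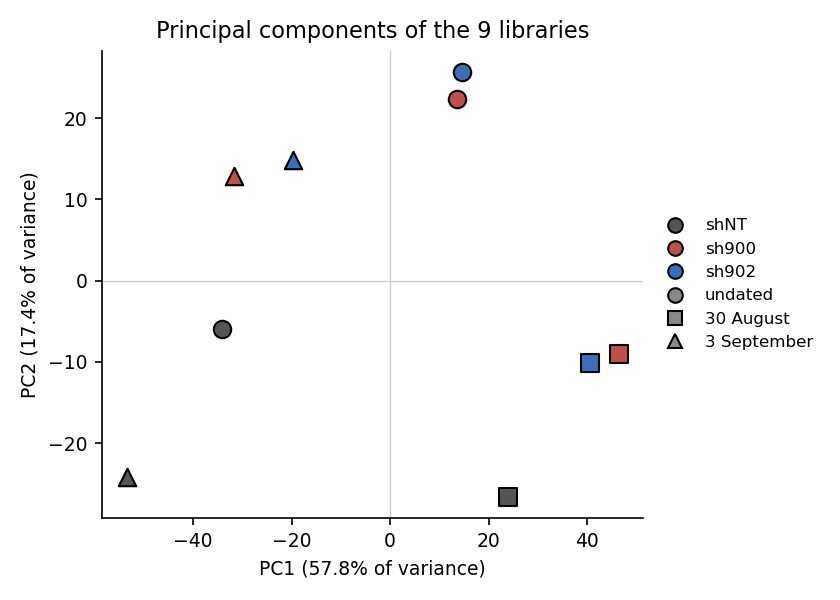
Scores of the 9 libraries on the first component (horizontal axis, 57.8% of variance) and the second (vertical axis, 17.4% of variance) of log2 CPM of the 500 most variable genes; colours mark the groups and shapes the date labels. Libraries of 30 August lie on the right and those of 3 September on the left, and the undated control lies left of both undated hairpin libraries.

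Genes changed by both hairpins were the main question. With the replicate block, and not without it, edgeR called 705 genes in the same direction with sh900 and with sh902, 440 higher and 265 lower, against 10 in opposite directions. In that fit the mean of both hairpins differed from shNT at 2054 of 17602 genes, 1070 higher and 984 lower. Genes higher with both included Shh, the gene of the secreted morphogen Sonic hedgehog, the transcription factor gene Tfap2c, the chromatin protein gene Hmga2 and Tlr4, which encodes the lipopolysaccharide receptor. Genes lower with both included Dcx, for a microtubule protein of migrating neuroblasts, the astrocyte water channel gene Aqp4, Gpr17, for a receptor of committed oligodendrocyte precursors, and the Notch ligand gene Dll3. Without a term for the date label, edgeR's quasi-likelihood test called 0 genes with both hairpins and 0 for their mean, although 2809 genes had an unadjusted p under 0.05 for the mean. On the same design DESeq2 called 755 genes for the mean and 159 with both hairpins, and limma-voom 0 for each. Reassigning the libraries within their date labels gave as many blocked calls in 1 of 80 assignments, the real one included, for the mean and for both hairpins. With the 6 dated libraries alone and the block, 1 gene was called for the mean of both hairpins and 0 with both. With only the groups compared in each blocked fit these counts were 865 and 0. Leaving out single libraries gave blocked counts for the mean of 218 without the undated shNT library, 3529 without the 30 August shNT library, 953 without the 3 September shNT library, 631 without the undated sh900 library, 997 without the 30 August sh900 library, 1460 without the 3 September sh900 library, 708 without the undated sh902 library, 2391 without the 30 August sh902 library and 832 without the 3 September sh902 library. For both hairpins the count ran from 46 without the undated sh902 library to 1786 without the 30 August shNT library.

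Because the fit without the block called no gene, the rule for naming genes was applied to the blocked fit, a choice made after seeing that. The 12 genes with the largest rise with both hairpins were led by Tnfsf18, a ligand of the TNF family, at a mean log2 fold change of 4.86 ± 0.66 (SE, edgeR adjusted p = 0.00731), and Tfap2c at 4.84 ± 0.86 (SE, adjusted p = 0.0175). Shh was near the floor with shNT, at 0.224 ± 0.144 CPM (SD, n = 3), and reached 3.47 ± 4.69 with sh900 and 11.9 ± 15.2 with sh902, a log2 fold change of 4.37 ± 0.51 (SE). Hmga2 went from 7.26 ± 9.49 CPM to 150.4 ± 210.2 and 47.1 ± 54.3 (SD, n = 3), with a log2 fold change of 3.43 ± 0.33. Tlr4 rose by 3.40 ± 0.39, the chloride channel gene Cftr by 3.56 ± 0.52 and the autophagy gene Atg9b by 3.40 ± 0.49 on the log2 scale. The interferon-inducible genes Ifi204 (4.55 ± 0.51) and Ifi202b (4.11 ± 0.44) rose as well, but they are close relatives of each other and of neighbouring genes, so reads could be split between copies. Liph, Tlcd2 and Tm4sf1 completed the set, with log2 fold changes of 3.54, 3.65 and 3.39. The 12 genes with the largest fall were led by the bone morphogenetic protein gene Bmp3 (-3.86 ± 0.70) and by Fxyd1 (-3.79 ± 0.57), a regulator of the sodium pump. Gpr17 fell from 148 ± 199 CPM to 31.5 ± 49.9 and 6.63 ± 9.11 (SD, n = 3), a log2 fold change of -3.61 ± 0.40 (adjusted p = 0.00731). Aqp4 had a log2 fold change of -2.59 ± 0.38, Dcx of -2.61 ± 0.41, Dll3 of -2.42 ± 0.30 and Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, of -2.67 ± 0.35. P4ha3, Lims2, Sema4a, Atp2b2 and Lypd1 lay between -3.18 and -2.40. Each of these 24 genes differed from the control of the same label in its direction in 6 of 6 hairpin libraries. Their selection as large blocked calls with both hairpins largely ensures this, so it is no further support. The group SDs include the differences between date labels, and none of the 24 was called without the block. Of the 116 blocked calls of named genes in all comparisons, 31 held with each library left out in turn and 85 were lost in at least 1 such fit. Below, genes whose call held in fewer than 5 of the 9 fits are given with that number.

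**Figure D3:**
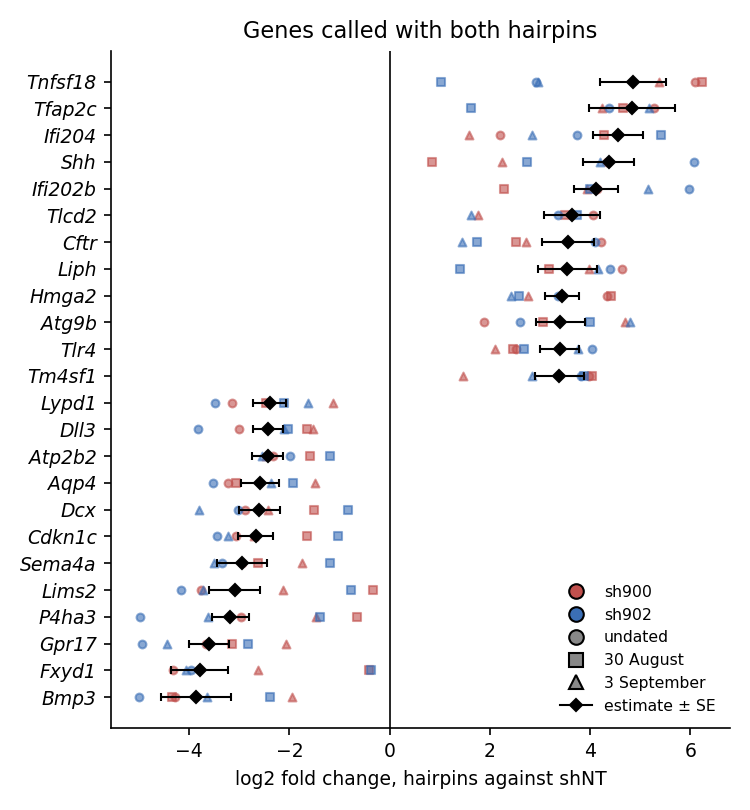
Log2 fold change (horizontal axis) of the 12 genes higher and 12 genes lower with both hairpins; black diamonds are the blocked edgeR estimates with their SE and coloured points the log2 CPM differences of each hairpin library from the control of the same label. Every point lies on the side of its estimate, as the selection of these genes by blocked calls largely ensures. The estimates run from -3.86 for Bmp3 to 4.86 for Tnfsf18.

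Targets of the tumour suppressor p53 were higher with both hairpins. In the blocked fit of the mean, the list fixed beforehand had 17 of 30 measured members higher and 1 lower (22 and 1 when adjusted over the list alone). Perp, a membrane protein gene of p53-dependent apoptosis, rose from 6.80 ± 3.09 CPM to 51.7 ± 20.0 with sh900 and 44.9 ± 22.1 with sh902 (SD, n = 3), a log2 fold change of 2.84 ± 0.15 (SE, edgeR adjusted p = 0.00104). The death receptor gene Tnfrsf10b had a log2 fold change of 2.12 ± 0.22, the kinase gene Plk2 of 1.62 ± 0.14 and the Akt regulator Phlda3 of 1.45 ± 0.14. The list's median ratio to the control of the same label was positive in 6 of 6 hairpin libraries, from 0.59 to 1.17 on the log2 scale. The list passed limma's camera test as higher without the block (camera adjusted p = 3.53e-07, and adjusted p = 0.511 with an estimated correlation). Camera values below also come from the fit without the block unless the block is named. Counts of members called higher or lower come from the blocked fit.

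Cell cycle genes lay on opposite sides of the control by date. Relative to the control of 30 August the median mitosis gene stood at -1.90 with sh900 and -1.61 with sh902 on the log2 scale, and relative to the control of 3 September at 2.36 and 2.83. The undated values were 0.47 and 0.60. DNA replication genes had medians of -1.59 and -1.29 on 30 August and 1.23 and 1.73 on 3 September. None of the 46 mitosis or 50 DNA replication genes was called in either fit. Camera placed both lists as higher without the block (mitosis adjusted p = 0.0247, DNA replication adjusted p = 0.0365). Their median edgeR log2 fold changes were negative, at -0.22 and -0.07, and their means also, at -0.21 and -0.09. These measures are unlike: camera averages log2 CPM over libraries, while edgeR compares fitted counts, in which a high library weighs more. The mean mitosis log2 CPM was 5.42, 6.87 and 3.11 in the undated, 30 August and 3 September controls, and 5.03 to 5.99 in the hairpin libraries. With an estimated correlation the adjusted p was 0.763 for both lists, and with the replicate block 0.0806 and 0.0961. Without the 3 September control both lists turned to lower (adjusted p = 1.98e-07 and 0.00775). Without the 30 August control both stayed higher (adjusted p = 6.08e-10 and 4.71e-14). The mitosis call was also lost, with adjusted p = 0.0906 without the undated sh900 library, 0.0694 without the 3 September sh900 library, 0.0673 without the undated sh902 library and 0.0733 without the 3 September sh902 library, and that of DNA replication with adjusted p = 0.322 without the undated shNT library, 0.156 without the undated sh900 library, 0.0694 without the 3 September sh900 library, 0.133 without the undated sh902 library and 0.0770 without the 3 September sh902 library. G1/S regulators, DNA repair genes and replication-dependent histones did not pass the camera test for the mean of both hairpins (adjusted p = 0.110, 0.506 and 0.292), and the median ratio of each was likewise negative on 30 August and positive on 3 September with both hairpins. These lists depended on the control kept. Without the 30 August control all 3 passed as higher (adjusted p = 1.77e-05, 5.52e-06 and 5.83e-06). Without the 3 September control DNA repair and histones passed as lower (adjusted p = 0.00537 and 9.21e-06). Among G1/S genes the blocked fit called the cyclins Ccnd2 (2.42 ± 0.49) and Ccnd3 (0.83 ± 0.17) higher and the kinase gene Cdk6 (-0.66 ± 0.17) lower, and among histones it called Hist2h3c1 higher (adjusted p = 0.0489), a gene with near-identical copies. These calls held for Ccnd2 in 2, Ccnd3 in 4, Cdk6 in 1 and Hist2h3c1 in 3 of 9 fits that left out 1 library each.

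Genes of neuronal and glial differentiation were lower for the mean of both hairpins. Without the block the oligodendrocyte, neuronal and astrocyte lists passed camera with sh902 (adjusted p = 2.59e-04, 4.69e-04 and 0.0181, and adjusted p = 0.568, 0.568 and 0.731 with an estimated correlation) but not with sh900 (adjusted p = 0.0591, 0.174 and 0.0881). With the replicate block they passed with sh900 too (adjusted p = 6.16e-04, 0.00978 and 0.00612, and adjusted p = 0.275, 0.617 and 0.617 with an estimated correlation). Of the oligodendrocyte lineage list, the blocked fit of the mean had 0 of 17 measured members higher and 8 lower (0 and 11 when adjusted over the list alone). Sox8, a transcription factor of the lineage, had a log2 fold change of -1.25 ± 0.18 (SE), the myelin gene Mbp of -1.91 ± 0.29 and the galactolipid synthesis gene Ugt8a of -1.84 ± 0.31. The list's median ratio to the control of the same label was negative in 6 of 6 hairpin libraries, from -2.21 to -0.74 (camera adjusted p = 0.00107, and adjusted p = 0.511 with an estimated correlation). Of the neuronal list, 1 of 30 measured members higher and 15 lower (3 and 18 when adjusted over the list alone) were called, among them Insm1 (-1.19 ± 0.16), Elavl3 (-1.55 ± 0.24), Dlx2 (-2.03 ± 0.33) and Sox11, which went from 280.1 ± 13.3 CPM to 152 ± 27.1 and 163 ± 49.7 (SD, n = 3). With sh900 alone the blocked fit called 1 member higher, the neurofilament gene Nefl, and 6 lower. The neuronal median was negative in 5 of 6 libraries and 0.18 with sh900 on 30 August (camera adjusted p = 0.00379, and adjusted p = 0.635 with an estimated correlation). The neuronal camera call was lost, with adjusted p = 0.169 without the 3 September shNT library. Of the astrocyte list, 1 of 18 measured members higher and 5 lower (1 and 12 when adjusted over the list alone) were called, the lower ones including the connexin gene Gja1 (-1.49 ± 0.30) and Apoe (-1.95 ± 0.42). Its median was negative in 6 of 6 libraries (camera adjusted p = 0.0156, and adjusted p = 0.690 with an estimated correlation), and the camera call was lost with adjusted p = 0.0748 without the undated shNT library, 0.400 without the 3 September shNT library, 0.0756 without the 30 August sh900 library and 0.0835 without the 30 August sh902 library. Neural stem and progenitor genes moved both ways, with 2 of 35 measured members higher and 8 lower (4 and 17 when adjusted over the list alone). The intermediate filament genes Nes (1.66 ± 0.21) and Vim (0.95 ± 0.15) rose, while the transcription factor gene Lhx2 (-0.72 ± 0.14) and Prom1 (-1.83 ± 0.38) fell. As a list they passed as lower (camera adjusted p = 0.0144, and adjusted p = 0.626 with an estimated correlation), a call lost with adjusted p = 0.101 without the undated shNT library and 0.0835 without the 30 August sh902 library. Calls of members named here held for Gja1 in 2 and Apoe in 4 of 9 fits that left out 1 library each. The controls themselves differed in these genes, with Gfap at 609.9, 8.77 and 1377 CPM in the undated, 30 August and 3 September libraries.

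**Figure D4:**
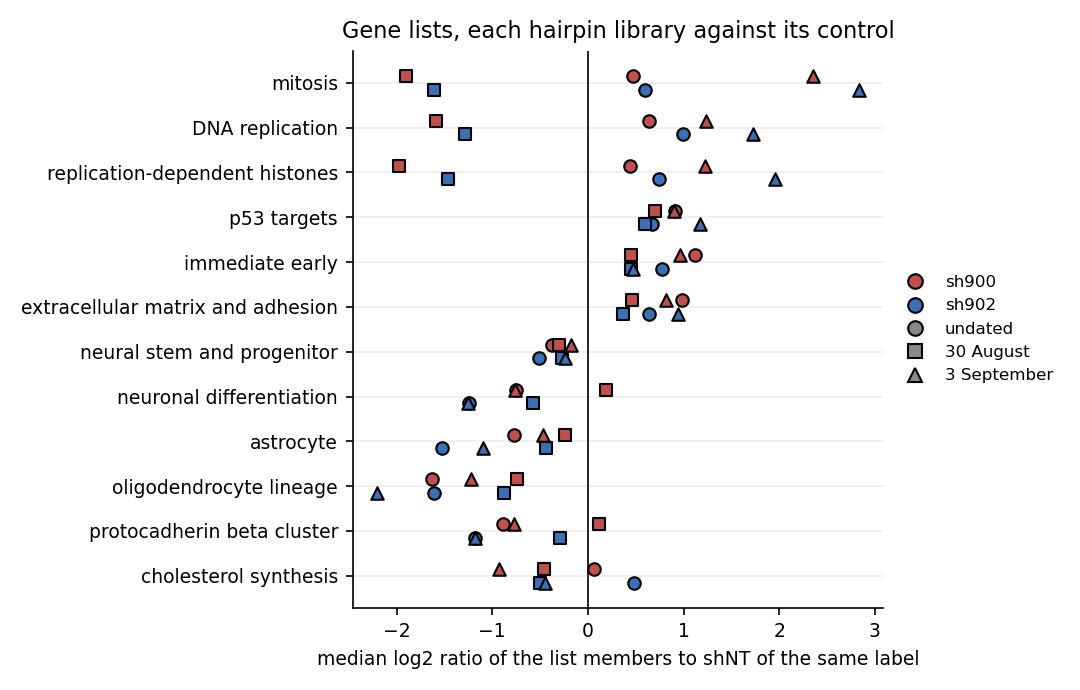
Median log2 ratio (horizontal axis) of the members of 12 gene lists (rows) in each hairpin library to the shNT library of the same label; colours mark the hairpins and shapes the date labels. Mitosis, DNA replication and histone lists lie left of 0 on 30 August and right of 0 on 3 September, p53 targets lie between 0.59 and 1.17, and the oligodendrocyte list lies between -2.21 and -0.74.

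Immediate early, adhesion and inflammatory genes were higher with the hairpins. Immediate early genes, which growth factors and stress induce, had 8 of 28 measured members higher and 0 lower (11 and 0 when adjusted over the list alone) in the blocked fit. The list passed as higher without the block (camera adjusted p = 3.06e-06, and adjusted p = 0.511 with an estimated correlation). The zinc finger genes Klf6 (1.49 ± 0.16) and Klf4 (1.48 ± 0.21), the AP-1 member Fosl2 (1.64 ± 0.18) and the phosphatase gene Dusp4 (2.32 ± 0.30) rose. Of the extracellular matrix and adhesion list, 17 of 44 measured members higher and 1 lower (20 and 3 when adjusted over the list alone) were called (camera adjusted p = 8.60e-04, and adjusted p = 0.511 with an estimated correlation), among them the hyaluronan receptor gene Cd44 (1.28 ± 0.15), Col5a1 (1.44 ± 0.19), Lamb1 (1.25 ± 0.17) and Itga3 (1.44 ± 0.22). NF-kB and inflammatory genes had 6 of 17 measured members higher and 0 lower (9 and 1 when adjusted over the list alone) (camera adjusted p = 8.60e-04, and adjusted p = 0.511 with an estimated correlation). The cytokine gene Lif rose by 2.25 ± 0.35, the chemokine genes Ccl2 and Ccl7 by 2.95 ± 0.51 and 3.00 ± 0.65 and Icam1 by 1.97 ± 0.37 on the log2 scale. Interferon response genes had 4 of 30 measured members higher and 0 lower (8 and 0 when adjusted over the list alone), namely Gbp3 (1.51 ± 0.33), Ddx58 (0.69 ± 0.16), Ifi44 (1.98 ± 0.44) and Irf7 (adjusted p = 0.0408). That list passed (camera adjusted p = 0.00248, and adjusted p = 0.690 with an estimated correlation), and its call was lost with adjusted p = 0.370 without the 30 August shNT library. Hypoxia and glycolysis genes had 7 of 29 measured members higher and 1 lower (9 and 1 when adjusted over the list alone) (camera adjusted p = 1.26e-04, and adjusted p = 0.511 with an estimated correlation). The vasodilator peptide gene Adm (1.81 ± 0.19), the phosphofructokinase gene Pfkp (1.96 ± 0.21) and Aldoa (0.93 ± 0.19) rose, and another phosphofructokinase gene, Pfkm (-0.59 ± 0.11), fell. Of the genes in this paragraph, calls held for Gbp3 in 4, Ifi44 in 3, Irf7 in 2, Ddx58 in 1, Ccl7 in 3 and Aldoa in 3 of 9 fits that left out 1 library each, and the others in at least 5.

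The clustered protocadherin beta genes, single-exon cell adhesion genes at chromosome 18, 37264938 to 37524479 on GRCm38, were lower. The blocked fit of the mean had 0 of 21 measured members higher and 9 lower (0 and 14 when adjusted over the list alone), including Pcdhb2 (-1.26 ± 0.21), Pcdhb5 (-1.05 ± 0.18), Pcdhb10 (-1.18 ± 0.22) and Pcdhb11 (-1.02 ± 0.17). The list's median was negative in 5 of 6 libraries and 0.12 with sh900 on 30 August (camera adjusted p = 8.86e-07, and adjusted p = 0.511 with an estimated correlation). These genes are similar to each other, so the count of any single one is uncertain. Of the cholesterol synthesis list, 0 of 23 measured members higher and 4 lower (0 and 5 when adjusted over the list alone) were called, with the synthase gene Hmgcs1 at -0.93 ± 0.15, Insig1 at -0.87 ± 0.17, Mvd at -0.84 ± 0.18 and Stard4 at -0.82 ± 0.19. That list passed as lower (camera adjusted p = 0.00149, and adjusted p = 0.635 with an estimated correlation), its call was lost with adjusted p = 0.276 without the 30 August shNT library and 0.0674 without the 3 September sh900 library, and its median was positive in both undated hairpin libraries. In the list of KDM7 relatives and H3K9 methylation genes, Cbx5, which encodes the heterochromatin protein HP1 alpha, fell from 1064 ± 271 CPM to 435 ± 141 and 676 ± 90.8 (SD, n = 3), and the demethylase gene Kdm4b had a log2 fold change of -0.47 ± 0.12. The list passed as lower (camera adjusted p = 0.0270, and adjusted p = 0.511 with an estimated correlation), and the call was lost with adjusted p = 0.101 without the undated shNT library, 0.0820 without the 30 August shNT library, 0.0694 without the 3 September sh900 library and 0.0660 without the 30 August sh902 library. Among integrated stress and unfolded protein response genes, the serine synthesis gene Phgdh (-0.84 ± 0.12) and the transporter gene Slc7a5 (-0.61 ± 0.11) fell and Edem1 (0.49 ± 0.11) rose, and the list did not pass (adjusted p = 0.198). Of the genes in this paragraph, calls held for Pcdhb10 in 4, Mvd in 4, Stard4 in 3, Cbx5 in 3, Kdm4b in 2 and Edem1 in 2 of 9 fits that left out 1 library each, and the others in at least 5. Cohesin and CTCF genes did not pass either (adjusted p = 0.198). In all, 17 of the 25 lists tested passed camera with its preset correlation of 0.01, 10 higher and 7 lower, 15 passed with the replicate block, and 0 passed with an estimated correlation. Of 100 random regroupings of the libraries, the real one included, 6 gave as many called lists, and of 80 regroupings within date labels, with the block, 8 gave at least the real 15.

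With sh900 alone, edgeR called 0 genes against shNT without the block (2585 at an unadjusted p under 0.05), DESeq2 786 and limma-voom 0, and with the replicate block edgeR called 1557, 949 higher and 608 lower. The next genes were called, and their 3 sh900 libraries all lay on one side of all 3 controls, a separation that chance gives for 10% of genes. Only genes already named for both hairpins were left out, so these may also be called with sh902. Those that rose most were the neurofilament gene Nefl of the neuronal list (6.09 ± 0.80), the serotonin receptor gene Htr1b (4.70 ± 0.53), the vitamin D hydroxylase gene Cyp24a1 (4.52 ± 0.50), H60b (4.22 ± 0.68) and the growth factor gene Pdgfb (3.87 ± 0.60). H60b has close relatives, so its count is uncertain. Those that fell most were Slc44a5 (-2.64 ± 0.33), the amino acid transporter gene Slc7a2 (-2.52 ± 0.28), Ptpn5 (-2.36 ± 0.38), Fxyd6 (-2.21 ± 0.38) and Plpp3 (-2.02 ± 0.24). Of the 25 lists 10 passed camera, 8 higher and 2 lower, 13 passed with the block, and 0 with an estimated correlation. With single libraries left out, 10 to 17 passed without the block. Without the 30 August shNT library 17 passed, 12 higher and 5 lower, 8 of them among the 10. Without the 3 September shNT library 11 passed, 6 of them among the 10. Among those called for the mean of both hairpins, the neural stem and progenitor (adjusted p = 0.156), KDM7 (0.162), mitosis (0.230) and DNA replication (0.467) lists and the 3 differentiation lists did not pass with sh900. The blocked count ran from 75 without the undated sh900 library to 2853 without the 30 August shNT library, was 4 with the dated libraries alone, and was 506 when the sh902 libraries were left out of the fit.

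With sh902 alone, edgeR called 0 genes against shNT without the block (2776 at an unadjusted p under 0.05), DESeq2 848 and limma-voom 0, and with the replicate block edgeR called 1850, 902 higher and 948 lower. The same rule was used, so the genes named may also be called with sh900. The genes that rose most were Fam135b (4.31 ± 0.37), the argininosuccinate synthase gene Ass1 (3.97 ± 0.23), the phosphodiesterase gene Pde1a (3.86 ± 0.41), the collagen gene Col8a1 (3.58 ± 0.38) and Ccdc153 (3.42 ± 0.37). Among those that fell most were Rdh9, the tubulin gene Tubb4a (-2.96 ± 0.41), the zinc finger gene Ikzf4 (-2.61 ± 0.52) and Pnma2 (-2.52 ± 0.59). Rdh9, a retinol dehydrogenase gene with close relatives, had 0 counts in all 3 sh902 libraries, which makes it at least 3.94-fold lower than with shNT when each sh902 library is set at a floor of 3 counts. Of the 25 lists 17 passed camera, 10 higher and 7 lower, 15 passed with the block, and 0 with an estimated correlation. With single libraries left out, 10 to 17 passed without the block. The lowest count, 3 higher and 7 lower, came without the 3 September shNT library. Replication-dependent histones, not called for the mean, passed as higher with sh902 (camera adjusted p = 0.0182, and adjusted p = 0.731 with an estimated correlation, and adjusted p = 0.0689 with the replicate block), while the mitochondrially encoded list did not pass (adjusted p = 0.0758). The call of Pnma2 held in 2 of 9 fits that left out 1 library each. The blocked count ran from 53 without the undated sh902 library to 3687 without the 30 August shNT library, was 0 with the dated libraries alone, and was 0 when the sh900 libraries were left out of the fit.

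The 2 hairpins were also compared directly. Without the block edgeR called 0 genes (2532 at an unadjusted p under 0.05), DESeq2 1035 and limma-voom 1. With the replicate block, 743 genes differed between them, 437 higher and 306 lower with sh900. Higher with sh900 were Rdh9, at least 27.7-fold against the floor of 3 counts per library, Cyp24a1 (3.20 ± 0.45), the neuronal migration gene Astn2 (3.20 ± 0.42), Car10 (3.02 ± 0.44) and the glutathione transferase gene Gstt3 (2.97 ± 0.44). Higher with sh902 were the neurokinin receptor gene Tacr1 (-3.29 ± 0.68), Fam135b (-2.86 ± 0.33), the guanine deaminase gene Gda (-2.79 ± 0.43), Ttn (-2.62 ± 0.36) and Dach2 (-2.53 ± 0.39). Of the 25 lists, replication-dependent histones were lower with sh900 than with sh902 (camera adjusted p = 0.0215, and adjusted p = 0.992 with an estimated correlation), with a median log2 difference of -0.51 and 0 of 65 members called. That call was lost with adjusted p = 0.391 without the 30 August sh900 library, 0.0845 without the 3 September sh900 library, 0.283 without the undated sh902 library and 0.0902 without the 3 September sh902 library, and 0.0533 with library size alone. With the replicate block 4 lists passed: neuronal differentiation (camera adjusted p = 0.00608), the oligodendrocyte lineage (0.0328) and protocadherin beta (0.0217) were higher with sh900, and histones (0.0217) lower. Each of the 4 had an adjusted p of 0.985 with an estimated correlation. Without the block, the number of lists called between the hairpins ran from 0 to 8 with single libraries left out. It was 0 without the undated sh902 library, 8 without the 30 August sh900 library, and 7 with no low-count filter. Among the genes named, calls held for Astn2 in 4, Car10 in 3, Gstt3 in 4, Tacr1 in 2, Gda in 4 and Dach2 in 4 of 9 fits that left out 1 library each. The blocked count fell to 0 without the undated or the 30 August library of either hairpin and with the dated libraries alone, was 1998 without the 30 August shNT library, the highest with 1 library left out, and was 2617 with the control libraries left out of the fit.

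Across genes, the effects of the hairpins were correlated. Their log2 fold changes had a Pearson r of 0.66 without the block and 0.67 with it, over 17602 genes, which are not independent replicates. Both contrasts use the same 3 controls, and 20 simulations of unchanged groups against such controls gave a mean r of 0.50 and 0.50. The covariance was 0.370 against 0.157 simulated without the block, a difference of 0.214, and 0.383 against 0.0875 with it, a difference of 0.296. The signs were the same for 70.8% of genes, and for 66.7% in the simulations. The 705 genes changed in one direction with both hairpins compare with at most 3 in any simulation, and with 48.6 higher and 32.7 lower for independent lists of the same lengths. Simulated genes vary independently, unlike real ones, so the simulated count is too low a standard. Reassigning the real libraries within their date labels gave up to 299 such genes, in a split that took the sh902 libraries as controls. Of 100 random regroupings of the libraries, the real one included, 29 gave an r at least as high, and of 80 regroupings within date labels, with the block, 14 did. With 3 control libraries the controls cannot be divided between the contrasts, so part of the excess may come from sharing them.

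Markers of other cell types varied in level. Csf1r, a microglial receptor gene, reached at most 0.670 CPM and the endothelial adhesion gene Pecam1 at most 0.641 CPM in any library, while the endothelial receptor genes Flt1 and Kdr reached 11.3 and 7.48 CPM. Only 2 of 15 microglia and macrophage genes passed the expression filter, so that list was not tested. One of them, Cd68, was called higher for the mean of both hairpins (1.04 ± 0.25), at 0.969 ± 0.390 CPM with shNT, 1.40 ± 0.650 with sh900 and 2.90 ± 1.02 with sh902 (SD, n = 3). The smooth muscle actin gene Acta2 stood at 11.2, 52.95 and 6.64 CPM in the undated, 30 August and 3 September controls, 148, 33.3 and 109 with sh900 and 52.0, 27.3 and 29.2 with sh902. Tagln, another smooth muscle gene, stood at 2.85, 2.62 and 3.62 CPM in the controls, 12.2, 1.15 and 24.8 with sh900 and 11.2, 1.62 and 11.5 with sh902. Fn1 reached 171 CPM and Prrx1 183 CPM, while the collagen gene Col3a1 was at 16.0, 11.1 and 8.55 CPM with shNT, sh900 and sh902 on 3 September and at most 2.44 CPM in the other libraries. None of Acta2, Tagln, Fn1, Prrx1 and Col3a1 was called. Endothelial and fibroblast lists did not pass camera (adjusted p = 0.292 and 0.353), and without the 3 September control the fibroblast list passed as higher (adjusted p = 0.0483). Kdr (-1.21 ± 0.29) and Pdgfrb (-3.37 ± 0.77) were called lower, and the calls held for Cd68 in 1, Kdr in 2 and Pdgfrb in 3 of 9 fits that left out 1 library each. The ependymal list did not pass (adjusted p = 0.164), with Ccdc153 (2.87 ± 0.34) and Rsph1 (1.63 ± 0.30) called higher. Foxj1, a transcription factor gene of ciliated cells, lay between 92.2 and 178 CPM in the 9 libraries.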

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

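The tests of scaling, of the control libraries, of single hairpins, of the share of pairs and of splits within date labels for the correlation and the lists were chosen after the results were seen; those of background reads, of random lists and of the other splits of the libraries were written down before.

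Cell cycle lists went opposite ways on the 2 dates with both hairpins. The gap between 3 September and 30 August in the mean of the hairpins' median log2 ratios to the control of the date was 4.35 for mitosis, 3.31 for histones, 2.92 for DNA replication, 2.62 for G1/S genes and 2.12 for DNA repair; the difference was not tested, since each date has 1 control library. Scaling of the libraries is argued against: a factor per library moves all genes alike, but the median gap per gene was 4.41 larger for mitosis genes than for all tested genes, whose quartiles ran from 4.14 to 4.55 and from -0.44 to 0.42. The state of the control libraries is a candidate explanation: the median mitosis gene changed by -3.87 (log2 CPM) between the controls of 30 August and 3 September, and by 0.37 and 0.63 between the sh900 and the sh902 libraries. A response to lower Phf2 that depends on the state of the culture cannot be told apart from this with 1 control library per date.

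Differentiation lists were lower with the hairpins in 17 of 18 pairs of list and library, as lower Phf2 would give. This count restates the pattern that prompted it, and the pairs share 3 controls, so it does not test that cause. For the oligodendrocyte list a single control library is argued against, since its call held without each control in turn (highest camera adjusted p = 0.0238 at the preset correlation; with all controls it was 0.511 with an estimated correlation, where the list was not called). For the neuronal and astrocyte lists this stays open: both remained lower but lost their calls without the 3 September control, with adjusted p up to 0.400. Background reads in silent genes were more frequent in 2 of the 3 controls. They are too few for the median loss of 31.4 CPM in the 28 members called lower, which was 342 times the level of olfactory and vomeronasal receptor genes in the controls. Those members were chosen by their loss, and members not called, which also enter the list medians, were not tested for this. A change in the share of differentiating cells and a change within cells could not be separated in these bulk libraries, where 17 of 18 medians were lower.

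The rise of p53 targets was present at all 3 date labels. The blocked median log2 fold change of 0.82 lay at percentile 100 of 10000 random lists matched on mean expression, whose central range ran from -0.13 to 0.20. These lists were drawn gene by gene, while the p53 targets had an estimated correlation of 0.36. A shift shared by correlated genes could exceed such lists too, so they do not exclude chance between libraries. The p53 list also had the smallest camera adjusted p of the 25 lists tested for the mean, a ranking that the random lists do not allow for. A single control library is argued against by a highest camera adjusted p of 7.73e-06 with each control left out. An off-target effect of 1 hairpin alone is argued against by the direct comparison of the hairpins, which uses no control: the members' median log2 difference was 0.012 (quartiles -0.18 and 0.32), where medians of 0.89 with sh900 or 0.86 with sh902 would be needed. The camera p-values use the preset correlation, and with an estimated one the list was not called. A p53 response to lower Phf2 stays open as a hypothesis, as does a p53 level particular to the 3 controls, which both contrasts share.

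The hairpins differed from each other in 743 genes with the replicate block, and in the list of replication-dependent histones without it (camera adjusted p = 0.0215, and 0.992 with an estimated correlation); the list call was lost with adjusted p = 0.391 without the 30 August sh900 library, 0.0845 without the 3 September sh900 library, 0.283 without the undated sh902 library and 0.0902 without the 3 September sh902 library, and 0.0533 with library size alone.

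Other splits of the libraries were refitted. With the replicate block, libraries were reassigned within their date label: of 80 such splits, the real one included, 1 gave as many genes as the real 2054 for the mean of both hairpins (highest other 1078) and 1 as many as the real 705 with both hairpins (highest other 299). In each case the highest other split was the one that took the 3 sh902 libraries as the controls, which keeps the real groups whole. Both shares are under 0.05, but these splits take the undated libraries, only possibly paired, as 1 block. With the dated libraries alone and the block the counts were 1 and 0, so these splits alone do not exclude chance. For the single blocked contrasts there are only 4 splits, too few for a share under 0.05: sh900 gave 1557, sh902 1850 and their difference 743 in 1 of 4 each, and 0 was the highest other. Without the block the real counts were 0, a value that any split reaches, so these shares were fixed in advance and test nothing. They were 100 of 100 drawn splits for the mean and for both hairpins. For each pair of groups they were 10 of 10, there also too few for a share under 0.05. The highest other split called 2188 genes for the mean; it set the undated and 3 September controls with the 3 September sh900 library against the rest, libraries at the negative end of the first component, so these calls follow a structure of the samples that the groups do not explain. For both hairpins the highest other was 32, in a split that set the 30 August libraries against the rest, for sh900 against shNT 2357, and for the other pairs 0. The correlation of hairpin effects of 0.66 was reached by 29 of 100 splits (highest other 0.92, with the 30 August libraries as the control group), and 17 called lists by 6 of 100 (highest other 17), so chance is not excluded for either. These splits mix date labels. Among the 80 splits within date labels, with the block, the real r of 0.67 was reached by 14 (highest other 0.87, in a split that kept the controls and mixed the hairpins) and the real 15 called lists by 8 (highest other 16, in a split that kept the controls together as a hairpin group), so chance is not excluded there either.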

How the results depend on the processing

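Counts of calls are given in the order sh900, sh902, mean of both, both hairpins, and sh900 against sh902; settings varied on top of the block (other than dated libraries), limma-voom and plain library size were chosen after seeing the data. Without the block all 5 counts were 0 and stayed 0 with RLE factors, plain library size, dated libraries alone and a 1.5-fold minimum. They became 786, 848, 755, 159 and 1035 with DESeq2, 58, 35, 8, 7 and 139 with no low-count filter, 0, 0, 0, 0 and 57 with at least 1 CPM in 3 libraries, 0, 0, 0, 0 and 1 with limma-voom, 0, 0, 1, 0 and 0 with only the groups compared, 1557, 1850, 2054, 705 and 743 with the replicate block and 4, 0, 1, 0 and 0 with dated libraries and the block. Leaving out 1 library gave 0 to 89; 0 to 7; 0 to 2; 0 to 0; 0 to 113. With the replicate block, the counts were 2590, 2833, 3014, 1262 and 1783 with DESeq2, 2209, 2419, 2716, 1008 and 1531 with no low-count filter, 506, 0, 865, 0 and 2617 with only the groups compared, 4, 0, 1, 0 and 0 with dated libraries and 0 with no replicate block; leaving out 1 library gave 75 to 2853; 53 to 3687; 218 to 3529; 46 to 1786; 0 to 1998. The other blocked settings stayed within 1.5 times. The Phf2 fold change stayed negative throughout; it was called with DESeq2 (-1.28) and the block (-1.32), and ran from -1.38 to -1.18 with single libraries left out. The correlation of hairpin effects became 0.69 with no low-count filter, 0.63 with dated libraries and 0.62 with dated libraries and the block, and 0.57 to 0.79 with single libraries left out. The 17 lists called for the mean of both hairpins became 0 with an estimated correlation, with or without the block, and 13 to 17 with single libraries left out. Without the 3 September control mitosis (adjusted p = 1.98e-07), DNA replication (0.00775), DNA repair (0.00537) and histones (9.21e-06) turned to lower, while without the 30 August control all 4, and G1/S genes (1.77e-05), were called higher; over the 9 fits that leave out 1 library, of either direction and lowest in that last fit, their adjusted p ran from 6.08e-10 to 0.0906, 4.71e-14 to 0.322, 5.52e-06 to 0.874 and 5.83e-06 to 0.997. Between the hairpins, ribosomal proteins turned to higher with sh900 without its 3 September library (adjusted p = 0.0227; range 0.00656 to 0.978). Of 116 calls of named genes with the block, none changed sign under any setting run; 31 held with each library left out in turn. Leaving out the undated, 30 August or 3 September library lost 66, 5 and 36 for shNT, 46, 34 and 21 for sh900 and 42, 17 and 32 for sh902, and calls were lost for 115 with dated libraries, 31 with only the groups compared and 116 without the block. Fewer libraries and residual degrees of freedom (6 without the block and 4 with it for 9 libraries) are part of the construction of these fits; beyond that, the cause was not tested. Depth limits genes under about 1 CPM.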

Other observations

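The counts of silent genes below were chosen for display after the results were seen. Of 77 measured cytosolic ribosomal protein genes, 1 was called with the block, Rps27l (0.79 ± 0.17, held in 2 of 9 fits that left out 1 library each), which is known as a p53 target, and the list's median log2 fold change was 0.17 (camera adjusted p = 0.00257, and adjusted p = 0.730 with an estimated correlation; the call was lost with adjusted p = 0.923 without the 3 September shNT library and 0.0836 without the 30 August sh900 library). None of the 13 mitochondrially encoded genes was called, with a list median of 0.27 (camera adjusted p = 0.00691, and adjusted p = 0.511 with an estimated correlation; the call was lost with adjusted p = 0.108 without the 30 August shNT library). Their share of all counts lay between 1.42% and 1.88% in the 9 libraries. Xist, the RNA of the inactive X chromosome, lay between 874 and 1689 CPM, while the Y-linked Ddx3y, Kdm5d and Eif2s3y had 0 counts in each library and Uty at most 1; the sex-linked list was not tested.

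Receptor genes taken here as silent in neural stem cells were detected unevenly. Of 1427 olfactory and vomeronasal receptor genes, 1102 had a count in the undated control and 1004 in the 3 September control, against 474 in the 30 August control and 126 to 552 in the hairpin libraries. The mean level of such a gene was 0.126, 0.0537 and 0.0958 CPM in the undated, 30 August and 3 September controls. All genes with a count numbered 31444, 26175 and 30614 in these controls and 23836 to 26747 in the hairpin libraries, at totals that overlap.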
